A study of Homo sapiens with 57 samples.

How the data were processed

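Gene expression was measured in 8 established human cancer cell lines on 57 one-colour Affymetrix arrays, in 19 groups of 3 arrays. The lines were A549, ACHN, HuT (written HUT78 in the treatment protocol), LOX (LOXIMVI), M14, MDA (MDA231), MiaPaca2 and PC3. Each line had a DMSO control and a group treated with romidepsin, an inhibitor of histone deacetylases, at 25 ng/ml (46 nM) for 6 h. A549, ACHN and MiaPaca2 also had a group at 18 h, described as 6 h with the drug and then 12 h in drug-free medium. There were 24 control arrays, 24 arrays at 6 h and 9 at 18 h.

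The labels do not fully match each other. The treatment text of 42 samples names a drug-free incubation of 42 h after treatment and an 18 h treatment of A549, ACHN and MiaPaca2. The series description and the text of the other 15 samples give 6 h, or 6 h followed by 12 h without the drug, and the times used here are the latter. The same 42 samples were grown with glutamine given in percent, and the 15 samples with glutamine given as a molarity. The 15 samples are all MiaPaca2 arrays and the 18 h arrays of A549 and ACHN. In A549 and ACHN, a comparison of 18 h with control or with 6 h therefore crosses these sets of samples, and time and set cannot be told apart there. All MiaPaca2 arrays belong to one set. The extraction text counts fewer cell lines than the labels name. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Controls carry a time of 0 h, and no DMSO arrays are labelled 6 h or 18 h. By the labels, time in culture and, at 18 h, the change of medium cannot be told apart from the drug, in MiaPaca2 too.

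The deposited values are linear signal intensity per probe set, made with MAS5 per the submitters' processing notes. Software version, detection calls and other steps are not given in the sources used here. The trimmed mean intensity was 149.97 to 149.98 on every array, so each array had been scaled to one target before deposit. Median signal per array ran from 14.6 to 26.8, with a middle value of 19.0. On the log2 scale used for testing, array medians spanned 0.49. The rule set beforehand kept the deposited scaling at a span under 0.5 and asked for median centring otherwise, so the deposited scaling was kept by a narrow margin. The number of arrays limits the precision, and no depth applies. No pair of columns held identical values. Every array had its highest rank correlation with an array of its own group (57 of 57).

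The table held 54675 probe sets, of which 62 were controls. A probe set was kept when its signal was above the array's 50th percentile on at least 3 arrays, which left 39522. In the annotation table, 41097 probe sets had 1 gene symbol, 1801 had several, and 11777 were not listed and are unnamed here. Symbols were updated through entrez identifiers with the RefSeq table of GRCh38.p14, and no coordinates were used. No gene was named from a probe set with several symbols. Where a gene had several kept probe sets, the brightest stood for it, which gave 16111 genes. Of 464 genes considered for naming, 272 had 2 or more kept probe sets. In the 6 h average, 7 had a probe set that changed in the opposite direction (HK2, IDI1, MDM2, POLR1A, POLR1B, RFC3 and SELPLG). The threshold for this was an unadjusted limma p under 0.05, and other comparisons were not checked.

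Signals were tested as log2(signal + 16). Fold changes are on that scale, which understates the change of dim genes. A single linear model with a mean for each of the 19 groups was fitted to all 57 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. The residual degrees of freedom were 38 and the median prior degrees of freedom 10.7. P-values were two-sided and adjusted over the 16111 genes by the Benjamini-Hochberg method within each comparison. A gene is said to be called, to rise or to fall at an adjusted p under 0.05, and genes past that threshold with at least a 2-fold change were counted as well. The comparisons were 6 h with control in each line, their mean over the 8 lines, an F test for differences of the 6 h effect among lines, the effect in HuT minus the mean of the other 7 lines, and 18 h with control and with 6 h in the 3 lines that had it. The design, the alternatives, the gene lists and the rule for naming genes were written before the data were examined.

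The 35 gene lists covered HDAC inhibitor induced genes, histone deacetylases, chromatin regulators, CDK inhibitors, G1 cyclins, DNA replication, mitosis, homologous recombination, pro- and anti-apoptotic genes, MAPK feedback, immediate early genes, receptor tyrosine kinases, histones, neuronal, epithelial and mesenchymal genes, MHC, interferon and NF-kB genes, drug efflux transporters, metallothioneins, cholesterol and fatty acid synthesis, ER stress, heat shock, the antioxidant system, p53 targets, ribosome biogenesis, glycolysis, cancer-testis antigens, ribosomal proteins, and markers of T cells, melanocytes and kidney epithelium. Each was tested with camera in limma at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. P-values were adjusted over the lists of a comparison.

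Named genes followed a fixed rule. They were the 10 largest rises and falls at 6 h among genes called the same way in all 8 lines, the 3 largest each way in each line, the 5 largest each way for HuT against the other lines, and the 4 largest each way for each comparison of the 18 h arrays. Outside the first part of the rule, a gene had to be called with a level in its higher group at least 1 log2 unit above the mean array median, and within a line the arrays of its groups had to be apart. Up to 4 called members of each discussed list and a set of genes known from HDAC inhibitor studies were added. Unnamed probe sets, LOC and open reading frame names, and Y-linked genes and XIST were passed over.

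Replicate numbers came from the sample titles. They were judged to pair arrays only where each same-numbered pair of arrays deviated together from the group means, with a correlation over 0.1. That held for control and 6 h arrays in LOX (correlations 0.293, 0.123 and 0.204), MDA (0.263, 0.118 and 0.210) and PC3 (0.365, 0.229 and 0.268), and in no other of the 14 group pairs. The reported fit paired no arrays in any line, and the block alternative used the numbers in every line. Alternatives were quantile normalization, centring each array on its median or on 9 hybridisation spike-in probe sets, pseudocounts of 1 and 64, no filter and a filter at the 70th percentile, the mean of probe sets, no intensity trend, a fit of the compared arrays alone, a block for line and replicate number, and leaving out each replicate or line. Median centring of the gene lists was added after seeing the data.

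The pipeline was tested on simulated arrays with known changes in 200 of the 16111 genes. For 6 h with control in A549 it recovered 49.3% of changes of 0.5 log2, 91.0% of 1 log2 and 100% of 2 log2, and called 8 unchanged genes. For the mean over lines it recovered 65.7% at 0.25 and 100% at 0.5, with 9 unchanged genes called. For HuT against the others it recovered 31.3% at 0.5, 92.5% at 1 and 98.5% at 2. For the F test these were 11.9%, 65.7% and 98.5%, and for 18 h against 6 h in MiaPaca2 38.8%, 94.0% and 100%. Of the 35 lists, the 1 shifted list was called and 0 others. The simulated genes varied independently of each other, so this cannot tell how the list test behaves where genes are correlated.

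The scalings moved the median of all genes in some comparisons. With median centring it shifted by −0.10 in A549 at 6 h, −0.18 in A549 at 18 h, −0.19 in ACHN at 18 h and −0.15 for 18 h against 6 h in ACHN. With spike-in centring it shifted by 0.17 in LOX, −0.11 in M14 and 0.49 in MDA at 6 h, by −0.16 in ACHN and −0.26 in MiaPaca2 at 18 h, and by −0.16 and −0.22 for 18 h against 6 h in ACHN and MiaPaca2. The spike-in probe sets averaged 10.3 ± 0.27 (SD, n = 3) on MDA control arrays and 9.81 ± 0.13 at 6 h on the log2 scale.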

Results

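The series set transcript levels after romidepsin, an inhibitor of class I histone deacetylases, against DMSO controls in 8 human cancer cell lines: A549 (lung), ACHN (kidney), HuT (T-cell lymphoma), LOX and M14 (melanoma), MDA (breast), MiaPaca2 (pancreas) and PC3 (prostate). Each of the 19 groups held 3 arrays, and signals are MAS5 intensities. In controls the T-cell markers averaged 8.65 ± 0.07 on the log2 scale (SD, n = 3) in HuT and 4.63 to 5.11 in the other lines, with CD3D, a subunit of the T-cell receptor complex, at a signal of 2766 ± 119 in HuT. The melanocyte markers averaged 10.74 ± 0.22 in M14 and at most 5.20 elsewhere, LOX included at 4.67. The kidney epithelium markers averaged 6.22 in ACHN and 6.17 in MiaPaca2.

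After 6 h, averaged over the 8 lines, the largest shared rise was that of DHRS2, a short-chain dehydrogenase, by 3.62 ± 0.12 log2 (SE), a 12.3-fold change, with adjusted p = 1.42e-31. In A549 its signal was 270.4 ± 186 in controls and 3045 ± 455 at 6 h (SD, n = 3). RGL1 (2.88), GRHL1 (2.72), FOS, a subunit of AP-1 (2.68), SERPINI1, which encodes neuroserpin (2.58), and CRISPLD2 (2.56) followed. Next were NEU1, a lysosomal sialidase (2.53), TPPP, a tubulin-binding protein (2.50), MXD1, a MAX partner that opposes MYC (2.46), and TUFT1 (2.41). The largest shared falls were ZFX (−2.32 ± 0.07, adjusted p = 1.87e-33), INO80D, a subunit of the INO80 remodelling complex (−2.19), ZMYND8 (−2.16), ADNP (−2.12), and BCAR3 (−2.08). They were followed by KEAP1, the adaptor that marks NRF2 for degradation (−2.06), ZBTB2 (−2.02), MSL1 (−2.01), JADE2 (−2.00) and ZBTB1 (−2.00). With the mean of probe sets INO80D stood at −1.08, ZMYND8 at −1.02, MSL1 at −1.17, ZBTB1 at −1.03, ZFX at −1.78 and TPPP at 1.23, and BCAR3, KEAP1 and ZBTB2 then had the largest falls of the 10. Of 16111 genes, 10036 were called by limma, 5557 up and 4479 down, against 4882 up and 5193 down with median centring. In the reported fit 541 of the rises and 244 of the falls reached 2-fold. In all 8 lines 1544 genes were called in the same direction, 848 up and 696 down, against 285 up and 164 down (449 in all) with spike-in centring and 684 up and 738 down with median centring.

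**Figure D1:**
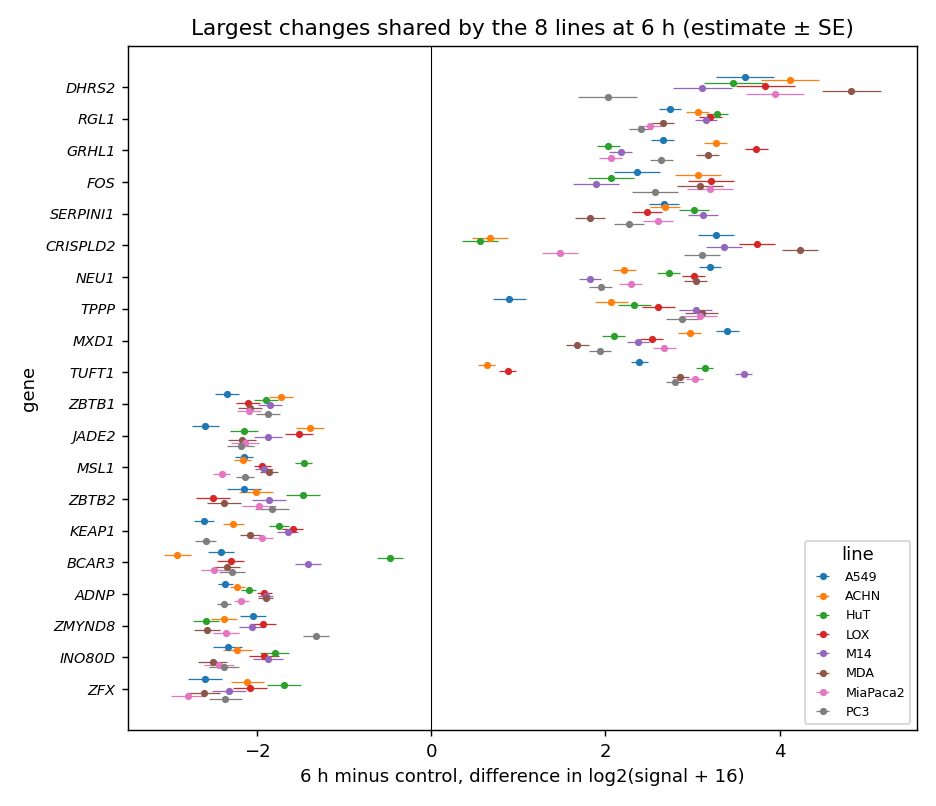
Difference between 6 h and control in log2(signal + 16) on the horizontal axis for the 10 largest shared rises and the 10 largest shared falls, with a point and SE for each of the 8 lines. All points of the upper genes lie right of 0 and all points of the lower genes left of it, with DHRS2 between 2.02 in PC3 and 4.83 in MDA.

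Genes known from other HDAC inhibitor work moved as follows in the 6 h average. CDKN1A, which encodes the CDK inhibitor p21, rose by 1.38, was called in 7 lines, and stood at −0.35 (not called) in ACHN, where a fit of the compared arrays alone called it as a fall. BCL2L11, which encodes the pro-apoptotic BIM, rose by 1.15, CLU by 1.36, GSN by 0.96 (0.58 with the mean of probe sets), TXNIP, an inhibitor of thioredoxin, by 0.87, TUBB3 by 0.35 and ABCB1, a drug efflux pump, by 0.26. MYC fell by 1.22 and was called in 7 lines, with −0.15 (not called) in MDA, where spike-in centring gave 0.33. CCND1, which encodes cyclin D1, fell by 1.11, CTPS1, a CTP synthase called in all 8 lines, fell by 1.07, and TYMS, thymidylate synthase, fell by 0.36. Of the deacetylases, HDAC3 rose by 0.79 and HDAC1 by 0.14, and HDAC2 fell by 0.09, a call that ended with quantile normalization and spike-in centring. Among other deacetylases, HDAC7 stood at −1.08 (another probe set at −0.26), HDAC5 at 0.80 (0.16) and HDAC11 at 0.60 (0.30).

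Genes of cholesterol synthesis rose together at 6 h. In the average 14 of 16 rose and 0 fell, with 2 not called, and 15 up and 1 down adjusted over the list alone. They were led by IDI1 (1.52, though another of its probe sets went the other way), INSIG1 (1.40), HMGCS1 (1.13) and STARD4 (1.01). Camera gave adjusted p = 3.84e-06, and adjusted p = 0.144 with an estimated correlation. Of 16 HDAC inhibitor induced genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with SYT11 at 2.20 and GLRX, glutaredoxin, at 1.65 beside DHRS2 (adjusted p = 0.00213; adjusted p = 0.144 with an estimated correlation). Of 25 neuronal genes, 21 rose and 0 fell, the same adjusted over the list alone, among them SCG2 (1.03), SYT1 (0.94), MAPT, which encodes tau (0.78), and SYN1 (0.73) (adjusted p = 0.00253; adjusted p = 0.196 with an estimated correlation). ER stress genes split into 16 rises and 3 falls of 22, adjusted over the list alone as well, with CHAC1 (1.38) and ERN1, which encodes the sensor IRE1 (1.26), up and TRIB3 (−0.97) down (adjusted p = 0.0114; adjusted p = 0.320 with an estimated correlation). In the MHC list 14 of 22 rose and 3 fell, adjusted over the list alone as well, and the largest changes were in the NKG2D ligands ULBP2 (1.65), MICA (1.35) and MICB (1.23) and in HLA-DMB (0.66) (adjusted p = 0.0424; adjusted p = 0.503 with an estimated correlation). IDI1 stood at 0.71, ERN1 at 0.69 and SYN1 at 0.40 with the mean of probe sets.

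Mitotic genes fell at 6 h. Of 27, 21 fell and 2 rose, adjusted over the list alone as well, including the kinases AURKA (−0.98) and PLK1 (−0.94) and the kinetochore genes NDC80 (−0.67) and CENPA (−0.66) (adjusted p = 0.000110; adjusted p = 0.503 with an estimated correlation). Of 25 chromatin writers and readers, 17 fell and 5 rose, adjusted over the list alone as well, with the histone methyltransferase SUV39H1 (−1.37), the acetyltransferases CREBBP (−1.28) and KAT5 (−1.02) down and the DNA methyltransferase DNMT3B up (1.36) (adjusted p = 0.000408; adjusted p = 0.0505 with an estimated correlation). In the DNA replication list 16 of 26 fell and 4 rose, adjusted over the list alone as well, with GINS3 (−1.13) and POLE2 (−0.66) down and CDC6 (0.74) and TK1 (0.70) up (adjusted p = 0.01003; adjusted p = 0.503 with an estimated correlation). Ribosome biogenesis genes gave 12 falls and 3 rises of 19, adjusted over the list alone as well, with RRS1 (−1.22), UTP20 (−0.66) and NOP16 (−0.66) down and RRP9 (0.68) up (adjusted p = 0.00756; adjusted p = 0.320 with an estimated correlation). Of 8 anti-apoptotic genes 6 fell and 1 rose, adjusted over the list alone as well, led by CFLAR, an inhibitor of caspase 8 (−1.21), BCL2L1, which encodes BCL-XL (−1.08), and XIAP (−0.91) (adjusted p = 0.0205; adjusted p = 0.196 with an estimated correlation). Of 18 NF-kB targets 11 fell and 5 rose, adjusted over the list alone as well, with LIF (−1.60), CXCL2 (−1.55), NFKBIA (−1.22) and NFKB1 (−1.11) (adjusted p = 0.0309; adjusted p = 0.503 with an estimated correlation). CREBBP stood at −0.77, CXCL2 at −0.997, NFKBIA at −0.71 and NOP16 at −0.40 with the mean of probe sets.

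The other 24 lists were not called by camera in the average. CDK inhibitors had 4 rises and 1 fall among 6 genes, with CDKN2D (2.37) and CDKN1C (1.80) above CDKN1A and CDKN1B at −1.08 (adjusted p = 0.123). Pro-apoptotic genes had 12 rises and 5 falls among 18, with BIK (1.70), CASP9 (1.15) and APAF1 (1.06) (adjusted p = 0.0857). The remaining adjusted p-values were 0.134 for the antioxidant system, 0.159 for homologous recombination, 0.196 for epithelial genes, 0.226 for histones, 0.258 for cytosolic ribosomal proteins, and 0.323 for p53 targets. They stood at 0.459 for immediate early genes, 0.504 for fatty acid synthesis, and 0.540 each for glycolysis, drug efflux transporters and kidney epithelium markers. They were 0.627 for receptor tyrosine kinases, 0.629 for G1 cyclins, 0.699 each for cancer-testis antigens and heat shock, and 0.708 for melanocyte markers. The highest were 0.754 for metallothioneins, 0.775 each for mesenchymal genes and histone deacetylases, 0.860 for MAPK feedback genes, 0.866 for T-cell markers and 0.914 for interferon response genes. The median and mean had opposite signs for receptor tyrosine kinases (−0.03 and 0.21), heat shock (−0.02 and 0.31), histone deacetylases (−0.02 and 0.06), interferon response (−0.03 and 0.09), MAPK feedback (−0.04 and 0.01) and cancer-testis antigens (0.00 and −0.02). T-cell markers had a median and mean of 0.06 and 0.08 with a downward test.

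**Figure D2:**
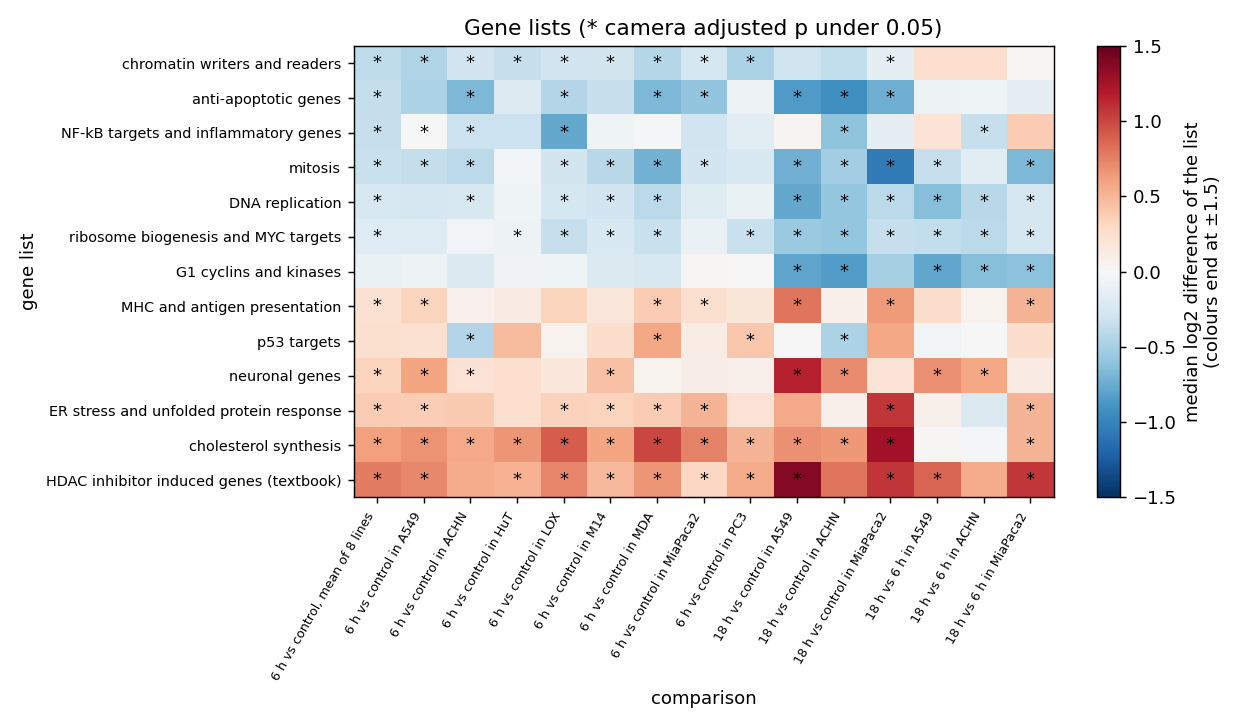
Median difference in log2(signal + 16) of the genes of each list, by comparison, from blue (lower) to red (higher), with asterisks where camera gave an adjusted p under 0.05 at the preset correlation. Cholesterol synthesis carries an asterisk in the average and in each of the 8 lines at 6 h, calls that were lost with an estimated correlation (adjusted p = 0.144 in the average), and G1 cyclins carry one in 2 of the 3 comparisons of 18 h with control and in all 3 of 18 h with 6 h.

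In A549 the largest rises at 6 h were LINC01511 (4.13), STC1, which encodes the hormone stanniocalcin (3.72), and DHRS2 (3.60), and the largest falls were EDN1, which encodes endothelin (−4.24), CYP24A1, the vitamin D 24-hydroxylase (−3.76), and PCED1B (−3.70). EDN1 had a signal of 1068 ± 44.0 in controls and 41.5 ± 5.10 at 6 h, and its fall was −1.10 with quantile normalization, where another of its probe sets was the brightest. Called genes numbered 6614, 3653 up and 2961 down, against 2799 up and 3613 down with median centring and 3676 in all with spike-in centring. In ACHN, DHRS2 (4.12), LINC01511 (3.69) and ST8SIA4 (3.46) rose most, and ZBED2 (−3.81), EDN2 (−3.34) and FOSL1, a FOS-family gene (−3.32), fell most. ST8SIA4 stood at 1.52 with the mean of its probe sets. There 5944 genes were called, 3541 up and 2403 down, against 3282 in all with spike-in centring. The p53 targets fell as a list in ACHN, with 11 falls and 5 rises of 20, adjusted over the list alone as well, AEN (−1.62), GDF15 (−1.48) and FAS (−1.41) down and TP53INP1 up (1.62) (adjusted p = 0.0135; adjusted p = 0.129 with an estimated correlation).

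In LOX, STC1 (4.20), DHRS2 (3.84) and CRISPLD2 (3.74) rose most. HAS2, a hyaluronan synthase, had the largest fall of any named gene in the 8 lines at 6 h (−5.59, adjusted p = 1.04e-26), from a signal of 3130 ± 413 to 49.0 ± 6.65, ahead of CXCL2 (−2.63, or −1.60 with the mean of probe sets) and HOXB2 (−2.56). LOX had 5997 called genes, 3472 up and 2525 down, against 3055 up and 778 down with spike-in centring. In M14, ARHGAP29 (4.12), TENT5C (3.72) and TUFT1 (3.59) rose, and MIR146A (−3.03), ZNF689 (−2.51) and RTP4 (−2.47) fell. ARHGAP29 stood at 1.18 with the mean of its probe sets. M14 had 5236 called genes, 3123 up and 2113 down, against 1215 up and 1371 down with spike-in centring. Of its 8 melanocyte markers 2 fell, adjusted over the list alone as well, SOX10 (−2.00) and MITF (−0.93), the transcription factors of the melanocyte lineage (adjusted p = 0.0369; adjusted p = 0.210 with an estimated correlation).

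In MDA, DHRS2 (4.83), CRISPLD2 (4.24) and GDF15, a stress-induced cytokine (4.06), rose, and HMGA2 (−3.81), PLAU, the urokinase (−3.39), and PDE4B (−2.88) fell. With the mean of probe sets HMGA2 stood at −0.92 in MDA and −0.73 in PC3, GDF15 at 2.32 in MDA and AQP3 at 2.58 in PC3, all called. Mitotic genes fell there in 23 of 27 cases with 0 rises, adjusted over the list alone as well (adjusted p = 8.01e-09; adjusted p = 0.330 with an estimated correlation). P53 targets rose in 14 of 20 and fell in 4, with 14 and 5 adjusted over the list alone, led by GDF15, TP53INP1 (2.73) and CDKN1A (1.98) (adjusted p = 0.00884; adjusted p = 0.0811 with an estimated correlation). MDA had 6408 called genes, 3548 up and 2860 down, against 7465 up and 473 down with spike-in centring. In PC3, AQP3, a water channel (4.25), CRISPLD2 (3.11) and TUBB2B (3.07) rose and HMGA2 (−3.72), HAS2 (−3.04) and NRIP1 (−2.89) fell. PC3 had 5292 called genes, 2711 up and 2581 down, against 2717 in all with spike-in centring. PC3 epithelial genes rose in 9 of 19 cases with 0 falls, adjusted over the list alone as well, led by CDH1, which encodes E-cadherin (1.51), and TJP3 (1.14) (adjusted p = 0.0134; adjusted p = 0.118 with an estimated correlation). In MiaPaca2, DHRS2 (3.95), GLRX (3.29) and FOS (3.20) rose and GAS1 (−3.10), ZFX (−2.79) and SOCS6 (−2.78) fell. MiaPaca2 had 5211 called genes, 2701 up and 2510 down, against 2575 in all with spike-in centring.

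**Figure D3:**
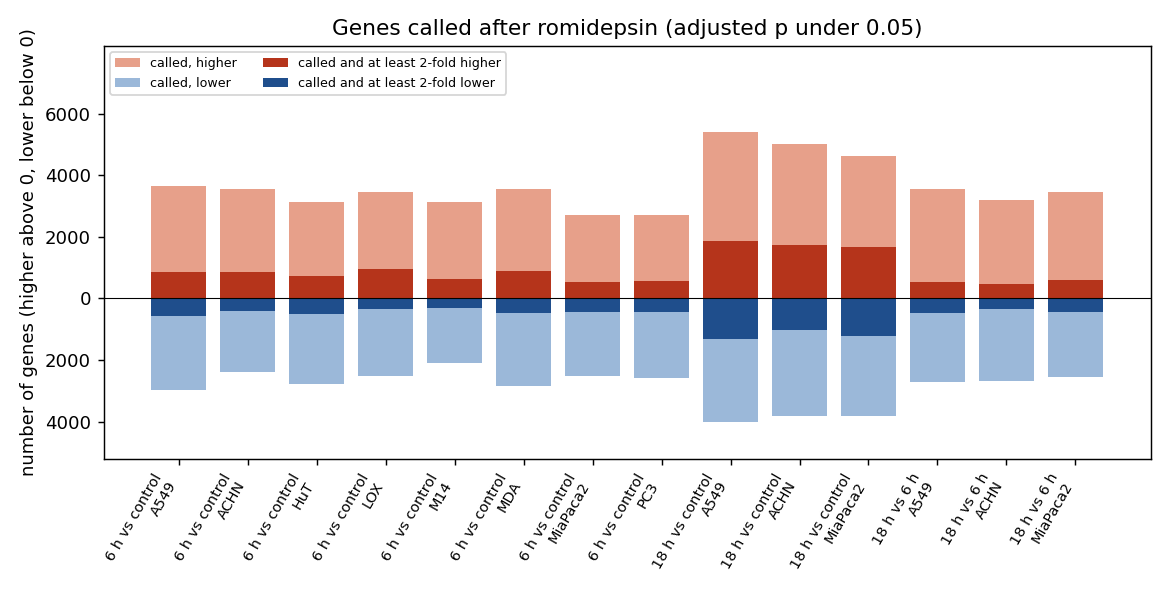
Number of called genes per comparison, higher above 0 and lower below 0, with the genes that changed at least 2-fold in the darker part of each bar. The 18 h bars of A549 (5389 up and 4020 down), ACHN (5007 and 3814) and MiaPaca2 (4613 and 3822) are longer than their 6 h bars.

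In HuT, ETV7, an ETS-family gene (4.52), DHRS2 (3.47) and BAIAP2-DT (3.36) rose most at 6 h, and NRROS (−3.71), the cytokine gene IL10 (−3.50) and GPR171 (−3.36) fell most. IL10 went from a signal of 314.2 ± 26.4 to 13.1 ± 2.86. With the mean of probe sets ETV7 stood at 2.42 and BAIAP2-DT at 2.09, below DHRS2 at 2.87. Called genes numbered 5894, 3128 up and 2766 down, against 3241 in all with spike-in centring. Set against the mean of the other 7 lines, the effect in HuT was higher for ID1 (2.99), FRMD6 (2.78), GJC1 (2.77), ETV7 (2.51) and ITPRIPL2 (2.40). ETV7 differed by 1.35 and GJC1 by 1.75 with the mean of probe sets. The effect in HuT was lower for IL10 (−3.53), SELPLG, the P-selectin ligand (−3.52), GPR171 (−3.46), LAX1 (−3.19) and NRROS (−3.13). In the 6 h average, SELPLG had a probe set that went the other way (−0.13 against 0.64). The naming rule asked for no level in the other lines, so the genes lower in HuT may have had little room to fall there. Within HuT, 6 of 16 T-cell markers fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.0423; adjusted p = 0.176 with an estimated correlation). Against the other lines the effect was lower in HuT for 6 of the 16 and higher for 1, with 9 and 1 adjusted over the list alone (adjusted p = 0.000544; adjusted p = 0.0120 with an estimated correlation). The largest differences were CORO1A (−2.57), GATA3 (−1.90), LAT (−1.58) and CD247 (−1.43). CORO1A, an actin-binding protein of leukocytes, stayed at 4179 ± 418 in HuT controls and 3846 ± 270 at 6 h and rose by 2.13 in the average of the 8 lines. Part of the list had little room to fall in the other lines, where CD247 had control signals of 6.99 to 10.0, under the lowest array median of 14.6. Mitotic genes were relatively higher in HuT for 11 of 27 with 0 lower, and 14 and 0 adjusted over the list alone (adjusted p = 0.000481; adjusted p = 0.853 with an estimated correlation). BCL2L11 stood at 0.03 (not called) in HuT and rose in the other 7 lines, a difference of −1.27 (adjusted p = 6.38e-09). Its level in HuT controls, a signal of 1766 ± 158, was above that of each other line at 6 h, 830.1 ± 125 in ACHN being the highest. CCND1 stood at 0.32 (not called) in HuT and differed by 1.64, but its signal of 9.66 ± 1.00 in HuT controls, under the array medians, left little room to fall. The difference was called for 3281 genes, 1532 higher and 1749 lower in HuT, against 378 and 721 with spike-in centring.

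The F test for a 6 h effect that differs among the 8 lines called 7272 genes, and 4535 with spike-in centring. The lines nonetheless correlated across genes, from r = 0.518 for ACHN with HuT to 0.712 for LOX with MDA, genes not being independent replicates. HuT had the lowest mean correlation with the others (0.569) and MDA the highest (0.676). Called in opposite directions in at least 1 line each were 1386 genes, and in at least 2 lines each 246. HuT also had the most genes that differed from the mean of the other lines (3281), and MiaPaca2 the fewest (1829).

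In A549 at 18 h, LINC01511 (6.69), MIR7-3HG (5.96), TXNIP (5.87) and CCDC13-AS2 (5.24) rose most against control. NRP1, a semaphorin and VEGF co-receptor (−5.10), CXCL5 (−5.05), KCTD15 (−4.64) and EDN1 (−4.43) fell most. NRP1 stood at −2.41, KCTD15 at −2.80, CDK6 at −1.23, CCND2 at 0.89 and ABCB1 at 1.00 with the mean of probe sets, and EDN1 at −2.29 with quantile normalization. TXNIP had a signal of 37.3 ± 27.6 in controls, 72.0 ± 22.7 at 6 h and 2847 ± 318 at 18 h. TYMS (−3.44, from a signal of 4703 ± 159 to 420.4 ± 29.1), CCND1 (−4.19), MYC (−2.64) and CTPS1 (−2.24) fell, and CDKN1A rose (1.34). Of 25 neuronal genes 20 rose and 0 fell, adjusted over the list alone as well, with the neurofilament gene NEFM (4.05), ELAVL3 (3.90) and DNER (3.83) (adjusted p = 4.30e-07; adjusted p = 0.0287 with an estimated correlation). DNA replication genes fell in 21 of 26 cases and rose in 2 (21 and 3 adjusted over the list alone), with MCM5 (−1.93) and MCM3 (−1.67) of the replicative helicase (adjusted p = 4.30e-07; adjusted p = 0.202 with an estimated correlation). G1 cyclins and kinases fell in 8 of 14 and rose in 3 (9 and 3 adjusted over the list alone), with CDK6 (−2.17) and E2F3 (−2.04) down and CCND2 (1.85) up (adjusted p = 0.00623; adjusted p = 0.0317 with an estimated correlation). Metallothioneins rose in 6 of 7 with 0 falls, adjusted over the list alone as well, MT1H by 2.30 and MT1F by 2.24 (adjusted p = 0.00597; adjusted p = 0.400 with an estimated correlation). Drug efflux genes went down in 5 of 7 and up in 2, adjusted over the list alone as well, with ABCC2 (−3.78) and ABCC3 (−2.50) down and ABCB1 (1.58) up (adjusted p = 0.00566; adjusted p = 0.0533 with an estimated correlation). Called were 9409 genes, 5389 up and 4020 down, and 4024 up and 5085 down with median centring. In A549 and ACHN the 18 h arrays belong to the other set of samples than the controls.

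In ACHN at 18 h, LINC01511 (6.10), DHRS2 (5.63), ABAT, the GABA transaminase (5.14), and PPM1E (5.004) were highest against control, and TM4SF18 (−4.31), NEXN (−3.97), NMI (−3.95) and NNMT (−3.91) lowest. TYMS (−2.02), CCND1 (−3.00), MYC (−1.60) and CTPS1 (−1.85) fell, and CDKN1A stood at 0.17 (not called). All 14 G1 cyclins and kinases were called, 12 down and 2 up, adjusted over the list alone as well, with CCND2 up (3.18, or 1.63 with the mean of probe sets) and CDK6 down (−1.76) (adjusted p = 0.000903; adjusted p = 0.00674 with an estimated correlation). DNA replication genes fell in 20 of 26 and rose in 1 (21 and 1 adjusted over the list alone), with MCM5 (−1.74) and MCM7 (−1.73) (adjusted p = 7.48e-07; adjusted p = 0.198 with an estimated correlation). NF-kB targets fell in 10 of 18 and rose in 2, adjusted over the list alone as well, with CXCL2 (−3.18), CXCL1 (−3.08) and IL6 (−2.53) (adjusted p = 0.000933; adjusted p = 0.358 with an estimated correlation). Called were 8821 genes, 5007 up and 3814 down, against 3641 up and 5076 down with median centring and 2800 up and 3522 down with spike-in centring.

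MiaPaca2, whose arrays lie in one set, had DHRS2 (6.21), PEG10, an imprinted gene of retrotransposon origin (6.17), MIR7-3HG (5.65) and SERPINI1 (5.38) as its largest rises at 18 h. Its largest falls were MALL (−3.91), KCTD15 (−3.86), JADE2 (−3.57) and IL27RA (−3.27), with KCTD15 at −2.01 for the mean of its probe sets. CDKN1A rose by 4.32, from 37.3 ± 7.16 to 1045 ± 54.8, TYMS fell by 2.51 and CCND1 fell by 2.67, and MYC stood at −0.07 (not called). Of 16 HDAC inhibitor induced genes 13 rose and 0 fell, adjusted over the list alone as well, with GLRX (4.90) and SYT11 (3.60) (adjusted p = 1.46e-05; adjusted p = 0.0377 with an estimated correlation). Cholesterol synthesis rose in 13 of 16 with 0 falls, adjusted over the list alone as well, INSIG1 by 2.67 and HMGCS1 by 2.34 (adjusted p = 2.43e-06; adjusted p = 0.152 with an estimated correlation). ER stress genes rose in 17 of 22 with 3 falls, adjusted over the list alone as well, DDIT3, which encodes CHOP, by 2.45 and CHAC1 by 2.55 (adjusted p = 1.46e-05; adjusted p = 0.118 with an estimated correlation). Mitotic genes fell in 21 of 27 with 0 rises (22 and 0 adjusted over the list alone), with AURKA (−2.41) and FOXM1 (−1.98) (adjusted p = 3.74e-07; adjusted p = 0.310 with an estimated correlation). Called were 8435 genes, 4613 up and 3822 down, against 2294 up and 4261 down with spike-in centring.

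**Figure D4:**
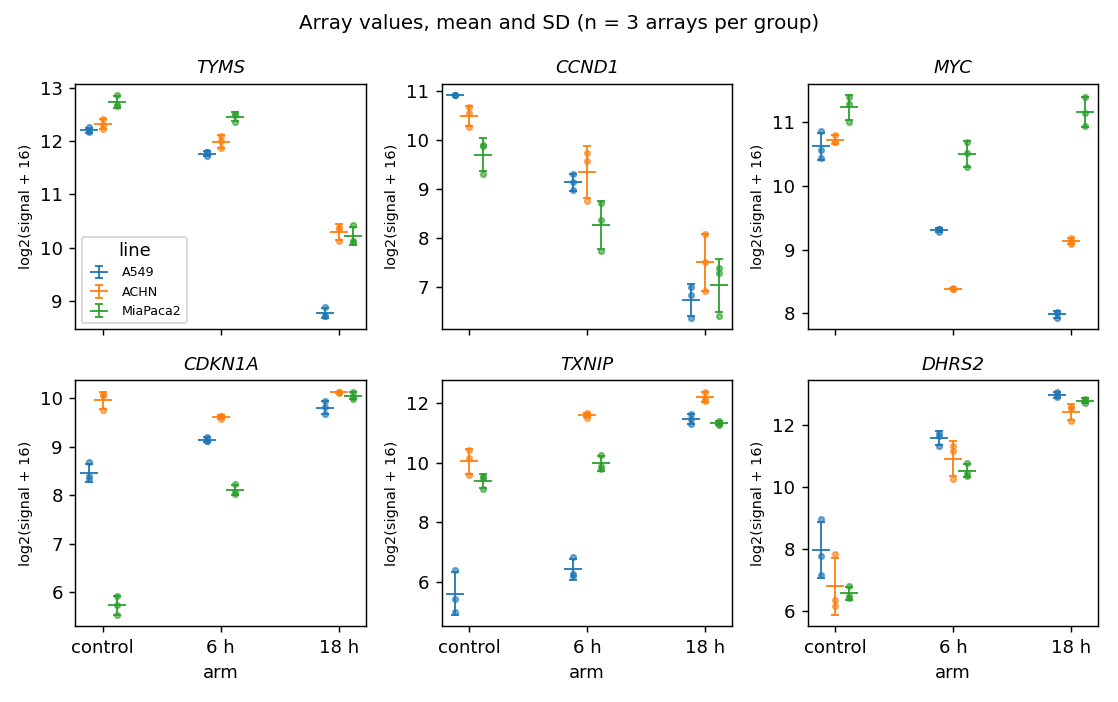
Values of 6 genes on the log2(signal + 16) scale in control, 6 h and 18 h arrays of A549, ACHN and MiaPaca2, with dots for arrays, horizontal marks for means and bars for SD (n = 3). TYMS lies lower at 18 h than at 6 h in the 3 lines, and MYC is lower at 18 h than at 6 h in A549 and higher in ACHN and MiaPaca2.

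Between 6 h and 18 h, TXNIP (5.05), MIR7-3HG (3.996), CCDC13-AS2 (3.69) and the histone gene H2BC4 (3.09) rose further in A549, and CXCL5 (−4.11), ANXA3 (−3.41), NRP1 (−3.38) and EMP1 (−3.15) fell. In ACHN, CYP1A1, a cytochrome P450 (3.44), ENPP2 (2.95), DNER (2.84) and CCDC13-AS2 (2.55) rose, and TM4SF18 (−3.49), LINC01111 (−3.13), ANXA3 (−3.01) and NNMT (−2.98) fell. In MiaPaca2, MIR7-3HG (4.53), PEG10 (3.67), CCDC13-AS2 (3.03) and CXCL2 (2.99) rose, and MALL (−3.08), NSMAF (−2.77), COL5A2 (−2.70) and SUMO3 (−2.65) fell. With the mean of probe sets NRP1 stood at −1.496, EMP1 at −1.29 and TYMS at −1.90 in A549, and NSMAF at −1.46 and CXCL2 at 1.99 in MiaPaca2. In A549, ACHN and MiaPaca2, TYMS changed by −3.00, −1.70 and −2.24, CTPS1 by −1.22, −0.92 and −1.05, and CCND1 by −2.41, −1.85 and −1.24. MYC changed by −1.33, 0.74 and 0.66, the last not called with spike-in centring (0.44). G1 cyclins and kinases fell in 9, 8 and 10 of 14 (10, 9 and 10 adjusted over the list alone) and rose in 1, 2 and 1 (2, 2 and 2), with adjusted p = 6.50e-05, 0.00101 and 0.00109, and adjusted p = 0.00113, 0.00872 and 0.0135 with an estimated correlation. Called were 6268 genes in A549 (3568 up and 2700 down), 5873 in ACHN (3190 and 2683) and 6033 in MiaPaca2 (3471 and 2562). With median centring the splits were 2695 up and 3197 down in A549 and 1861 and 3868 in ACHN, and with spike-in centring 2113 and 1159 in A549, 850 and 2041 in ACHN and 949 and 2479 in MiaPaca2.

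Of the genes that rose at 6 h in A549 (3653), ACHN (3541) and MiaPaca2 (2701), 3135, 3020 and 2448 were up at 18 h as well, and of the falls (2961, 2403 and 2510), 2379, 1928 and 1985 were down. Independent lists of those sizes would share 1222, 1100 and 773 rises and 739, 569 and 595 falls. Simulated unchanged groups on the same controls shared 0, a count set in advance because hardly any gene is called without a change. It cannot tell how many shared calls the controls add. The covariance of the effects was 0.414, 0.359 and 0.325, against simulated covariances of 0.0145, 0.0146 and 0.0146. Of the 6 h rises, 1332, 1279 and 1354 rose further from 6 h to 18 h and 466, 484 and 156 fell back, where independent lists would give 809, 701 and 582, and 612, 590 and 430. Of the 6 h falls, 929, 715 and 870 fell further and 628, 473 and 497 went back up, where independent lists would give 496, 400 and 399, and 656, 476 and 541. These comparisons share the 6 h arrays. Simulated unchanged groups shared 0 calls in either direction, a count likewise set in advance that cannot decide. Their covariances were −0.0146, −0.0146 and −0.0145, against 0.0624, 0.0521 and 0.0729 observed. The 3 controls of a line were too few for 2 sets of at least 2 arrays, so part of the excess in shared calls may come from shared controls, whose part in the covariance is the simulated value.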

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

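Chosen only after the result was seen were the ratio of counts in MiaPaca2, the scaling test of the 18 h counts, both tests of median centring on the share of rises, the test by level of the 2-fold changes, and the splits for differences between lines. Groups of 3 arrays were not tested for a sample far from the others.

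The 6 h effect differed among the 8 lines for 7272 of 16111 genes by the F test (4535 with spike-in centring), and for 77 of the 83 genes named by size, many of them picked for a large effect in 1 line or for a difference between HuT and the others. Some named genes rose in at least 2 lines and fell in at least 2, a restriction set after their calls had been seen. ARHGAP29 rose by 4.12 in M14, 2.86 in LOX and 2.69 in HuT and fell in ACHN (−0.98), with an F test adjusted p = 3.25e-34. With the mean of its probe sets ARHGAP29 stood at 1.18 in M14, 0.76 in LOX and 0.75 in HuT, called in each. EDN1 fell in A549 (−4.24) and MDA (−2.44) and rose in LOX (0.86) and PC3 (0.65) (adjusted p = 6.64e-23), but with quantile normalization, where another probe set of EDN1 was the brightest, LOX stood at −0.05 and PC3 at 0.05, neither called, and the falls were −1.10 in A549 and −0.51 in MDA, both called. The EDN1 call in PC3 also ended with spike-in centring (0.63) and without control replicate 1 (0.50), and those in LOX (0.03), PC3 (0.09) and MDA (−0.72) with a pseudocount of 1, again on that other probe set, where A549 stood at −1.17. FRMD6 rose in HuT (2.74) and fell in ACHN (−0.90) and LOX (−0.82) (adjusted p = 3.56e-24). GAS1 rose in LOX (1.23, or 0.60 with the mean of probe sets) and fell in MiaPaca2 (−3.10) and M14 (−1.75) (adjusted p = 5.41e-20). ID1, an inhibitor of differentiation factors, rose in HuT (2.83) and ACHN (1.26) and fell in MiaPaca2 (−1.08) (adjusted p = 1.58e-19). The effect in HuT differed from the mean of the other 7 lines for 3281 genes (1099 with spike-in centring), and for the T-cell markers as a list with adjusted p = 0.01205 when the correlation was estimated, though part of that list lay under the array medians in controls of the other lines, with little room to fall there. Arrays at 18 h differed from those at 6 h for 6268 genes in A549, 5873 in ACHN and 6033 in MiaPaca2 (3272, 2891 and 3428 with spike-in centring). Outside the named genes, 3441 of 7489 probe sets without a single gene symbol were called in the 6 h average, 1806 up and 1635 down.

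Other splits of the same arrays were counted for each comparison. For the 6 h average, 1 of 100 splits, the real one, gave as many genes as 10036, and the highest other gave 3420, so a chance labelling of these arrays is excluded. The 1544 genes shared by the 8 lines were reached by 1 of 100 splits (highest other 0). A split that mixes the groups of any line leaves few calls in that line. A count near 0 was therefore set in advance, and this test cannot decide. For differences between lines, the arrays were split with the shared effect taken out and added to the arrays then labelled 6 h. The 7272 genes of the F test were reached by 1 of 100 such splits (highest other 3145), so a chance labelling of these arrays is excluded. If replicates are technical, none of these splits can exclude chance differences between cultures. For HuT against the others, the 3281 genes were reached by 1 of 10 splits of the HuT arrays (highest other 23). In the first splits the shared effect had been left in. There 2 of 100 reached 3281 for HuT, the highest other being 4015. That count came from 7 splits that left the HuT groups whole, and with those groups mixed the highest was 5. For the F test, 1 of 100 first splits reached 7272 (highest other 5140). In each of the 14 comparisons of 3 arrays with 3, the real split was 1 of 10 and no other gave as many genes, with the highest other from 3 (A549 at 18 h) to 326 (LOX at 6 h). With 10 splits the share cannot go under 0.05.

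More genes were called at 18 h than at 6 h against control in the 3 lines. A difference between the sets of samples could account for this in A549 and ACHN, but not in MiaPaca2, whose arrays lie in one set and whose count at 18 h was 1.62 times that at 6 h. Scaling was excluded as the cause, since the lowest ratio over quantile, median and spike-in scaling was 1.41. In A549 and ACHN the effects from 6 h to 18 h correlated across genes by 0.587, and with MiaPaca2 by 0.536 and 0.497, an excess of 0.071 that leaves set and time not to be told apart there. The longer time, and the drug-free interval, stay open as biological explanations that the design does not separate. Time in culture and the change of medium stay open as well, since no DMSO arrays are labelled 18 h.

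More genes rose than fell in the 6 h average, but with median centring 48.5% of called genes rose, so the excess over all called genes may come from the scaling of the arrays. Among genes with at least a 2-fold change, 62.3% rose with median centring and 68.9% in the reported fit, so scaling is excluded as the whole cause there. Split into 3 equal parts by level over all arrays, 51.4% of the called genes rose in the brightest part and 64.1% in the dimmest. With the level set by control arrays these were 45.2% and 74.8%, so room for dim genes to rise stays open. Of the 2-fold changes 65.0% rose in the brightest part, but 40.2% where the level was set by control arrays (exact binomial interval 34.4% to 46.3%, genes not being independent), so room to rise may account for that excess as well. The control arrays also enter the 6 h effect, which by itself places falls in the bright part and rises in the dim part. How much this adds was not tested. No biological explanation was tested.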

How the results depend on the processing

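With spike-in centring the counts of called genes moved by over 1.5 times in 13 of 19 results: 6 h with control gave 3676 genes in A549, 3282 in ACHN, 3241 in HuT, 3833 in LOX, 2586 in M14, 2575 in MiaPaca2 and 2717 in PC3, HuT against the other lines 1099, 18 h with 6 h 3272 in A549, 2891 in ACHN and 3428 in MiaPaca2, the genes shared by 8 lines 449 and the F test 4535. The cause was not tested. No count moved by that much with quantile normalization, median centring, other pseudocounts, other filters, the mean of probe sets, no intensity trend or a fit of the compared arrays alone, nor in the 276 fits without a replicate and the 31 without a line. Leaving out each replicate in turn gave 9936 to 10026 called genes for the 6 h average, 2693 to 3340 for HuT against the others, 1441 to 1550 for the genes shared by 8 lines and 7040 to 7361 for the F test.

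For the gene lists, camera made 144 calls, of which 15 were kept with an estimated correlation, and fry made 370 calls, keeping all 144, though it does not compare a list with other genes. Quantile normalization kept 136, median centring 141, spike-in centring 139 and the replicate block 142, with 0 directions turned. Cytosolic ribosomal proteins in MDA at 6 h (adjusted p = 0.00320) went to 0.670 with quantile normalization and 0.381 with spike-in centring, and ribosome biogenesis in MDA to 0.0532 and 0.211. DNA replication for HuT against the others went to 0.0596 and 0.0558. The replicate block ended calls of anti-apoptotic genes in MiaPaca2 at 6 h (0.0580) and 18 h (0.0587), where same-numbered arrays did not all correlate over 0.1. It gave 10337 called genes in the 6 h average, moved no count by over 1.5 times, and among the named values added a call of CDKN1A in ACHN (−0.35) at 6 h. CDKN1A in ACHN was also called in a fit of the compared arrays alone. Same-numbered arrays correlated over 0.1 throughout in LOX, MDA and PC3 alone of the lines. In other lines pairing by number was not shown, though each of the 3 arrays correlated best with its own number in ACHN and HuT at 6 h and in MiaPaca2 at 18 h.

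Of the named values called in the reported fit, 39 were over 1.5 times smaller with the mean of probe sets and 35 with a pseudocount of 64, and with a pseudocount of 1 there were 15 larger and 5 smaller. Quantile normalization made 6 smaller, spike-in centring 2 and median centring 0. EDN1 in LOX turned to −0.046 with quantile normalization, where another probe set stood for it. Values not called in the reported fit changed sign for CDKN1A in ACHN at 18 h (−0.023 with median centring) and MYC in MDA (0.33 with spike-in centring). Without each replicate in turn, BCL2L11 in HuT ran from −0.042 to 0.082 and MYC in MiaPaca2 at 18 h from −0.188 to 0.041. Calls ended for HDAC2 in the 6 h average with quantile normalization (−0.04) and spike-in centring (−0.03), and for MYC between 6 h and 18 h in MiaPaca2 with spike-in centring (0.44). CD247 in HuT against the others lost its call with a pseudocount of 1 (−1.62).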

Other observations

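The heat shock and histone lists, not called in the 6 h average, were called at the preset correlation at 18 h in A549 and ACHN, heat shock against 6 h and histones against control, and none of these calls held with an estimated correlation. HSPA2, a testis-enriched member of the HSP70 family, rose by 2.24 in the 6 h average, and by 4.06 in MiaPaca2, 1.85 in ACHN and 1.46 in A549 at 18 h. Of the 10 heat shock genes, 7 fell between 6 h and 18 h with 0 rises in A549, the same adjusted over the list alone, HSPH1 (−1.71) among them (adjusted p = 1.18e-05; adjusted p = 0.0684 with an estimated correlation), and 6 of 10 with 0 rises in ACHN (7 and 0 adjusted over the list alone), with DNAJB1 (−0.79) and HSPH1 (−0.77) (adjusted p = 0.000103; adjusted p = 0.126 with an estimated correlation). Histone genes rose at 18 h in 9 of 12 cases with 2 falls in A549, the same adjusted over the list alone (adjusted p = 0.0150; adjusted p = 0.259 with an estimated correlation) and likewise in ACHN (adjusted p = 0.0389; adjusted p = 0.362 with an estimated correlation). H2BC21 rose in A549 (4.40), ACHN (3.38) and MiaPaca2 (2.24). In A549 and ACHN these comparisons cross the sets of samples, so time and set cannot be told apart.

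Single genes of other lists also moved in the same direction in the 3 lines at 18 h. BID, a pro-apoptotic BH3 protein, fell in A549 (−2.05), ACHN (−1.92) and MiaPaca2 (−2.00), and the death receptor FAS fell as well (−1.96, −2.79 and −1.97). PMEL, a melanosome protein, rose in A549 (3.35), ACHN (3.31) and MiaPaca2 (3.76), none of which is a melanoma line. SYT1, a synaptic vesicle protein, rose in ACHN (3.02) and fell in MiaPaca2 (−2.35), a difference that was not tested.

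The test of marker genes was set before its result was seen. The lower effect on T-cell genes in HuT than in the other lines led to a test of whether genes that mark a line in its controls fall more than others there at 6 h. In each line the 200 genes most specific to it on control replicate 1 were set against 200 genes of like level. The latter were drawn only from genes within 1 log2 of the mean of the other lines on that replicate. Whether such genes differ from the markers in further traits was not tested. With the effect from control replicates 2 and 3, the markers fell more in 8 of 8 lines (exact two-sided sign test p = 0.00781; 7 of 7 without HuT, p = 0.0156). The median difference was −0.216 log2, from −0.126 in PC3 to −0.536 in HuT, so choosing the genes on the same control arrays is excluded as the cause. If replicates are technical, a deviation that all control arrays of a line share is not excluded. A hypothesis is that the drug may lower genes tied to the identity of each line, which these data alone do not establish.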
